A study of Homo sapiens with 8 samples.

How the data were processed

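RNA from 8 clonal isolates of PC-3, a human prostate cancer cell line, was measured on 8 Affymetrix arrays, 1 array per clone. Total RNA had been purified with RNeasy columns and DNase and labelled with biotin, per the labels. Each clone had been assigned by its label to 1 of 2 groups. The RWDD4 group held the 4 clones that carried a lentiviral vector with RWDD4 (clones 17, 24, 5 and 6), and the control group the 4 clones that carried the empty vector (clones 2, 3, 4 and 5).

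The values used were log2 values deposited by the authors, 1 per probe set and array, and the submitters' processing notes name Partek and RMA, without a version or settings. RMA corrects the background, normalizes the arrays to each other and summarises the probes of a probe set on a log2 scale. Such values compare a gene between arrays; they do not set the level of 1 gene against another, and small fold changes near the background are compressed. Genome build, scan dates and batches are not given in the sources used here, and signal over background per probe was not analysed here. No 2 arrays held identical values. The number of arrays limits the precision.

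The table held 53617 probe sets. The annotation used paired 16098 of them with exactly 1 gene symbol, none with several, and left 37519 unlisted, which does not mean that they measure no gene. The 16098 probe sets stood for 14884 genes, all of which were found by gene ID in a human reference gene table (assembly GRCh38.p14) that was used for current symbols, gene type, genomic span and neighbouring genes, not for coordinates. Of these genes, 779 had more than 1 probe set; the probe set with the highest mean over all 8 arrays stood for the gene. For 12 genes the probe sets passed the test in opposite directions. No filter on dim probe sets was applied.

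The comparison was RWDD4 clones minus control clones, fitted for all genes at once with lmFit and eBayes of limma 3.58.1 in R 4.3.3, without covariates, two-sided, with Benjamini-Hochberg adjustment over the 14884 genes. A gene is said to have risen, fallen or changed when its adjusted p was under 0.05. RWDD4 itself was also tested by an exact permutation test over the 70 relabellings of the 8 clones. Errors are standard deviations over the 4 clones of a group (SD) or standard errors of the difference from the fit (SE). Fold values are the fitted differences on the log2 scale turned to folds.

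The following choices were made before the data were examined. Apart from RWDD4, the genes named were the 12 per direction with the largest difference among those that passed the test with no overlap between the groups, leaving out symbols of the LOC, LINC, MIR and orf kind and of other non-coding or pseudogene names; 2 such genes higher and 3 lower in the RWDD4 clones were passed over. From each of 37 gene lists up to 4 members were named in addition. Lists with at least 4 measured members were tested with camera of limma, with the correlation between genes estimated from the residuals and Benjamini-Hochberg adjustment over the 34 lists tested; a preset correlation of 0.01 and fry, a rotation test, were alternatives. Camera asks whether a list's genes differ more than other genes do, and fry asks whether they move on balance in 1 direction. A list's members were also counted after adjustment over the list alone. Other members of the lists are named for their place in a group and were chosen after their values were seen.

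Alternatives covered the variance model, the probe set that stands for a gene, a filter on the mean level, 3 further scalings, array weights, all probe sets in place of genes, and leaving out each clone. After the data had been seen 2 more were added: removing each array's lowess trend (span 0.3) over log2 genomic span, and a fit in which each array's position on the leading axis of within-group variation was a covariate.

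The steps were tested on simulated data with the values and spread of these arrays, for the comparison of RWDD4 with control clones over 14884 genes. Of the genes changed by 0.5, 1 and 2 log2 units, 43.3%, 94% and 100% were recovered, and 17 of 175 calls were false. Camera called 5 of 5 lists shifted by 0.5 and 0 of 29 unshifted lists. The simulated genes varied independently of each other, so the power of camera for lists of correlated genes was not measured. A simulated span trend with no other difference gave 5896 calls, and 0 after its removal. When the axis found in these arrays was the only difference, 5941 genes were called without the covariate and 0 with it. The simulated trend and axis had the form that each correction removes. These results do not show that a bias of another form would be removed. The fit with the covariate recovered 95% of genes changed by 2 log2 units. Those genes and their directions were picked at random. The real group difference ran along the axis (r = -0.76 across genes with the axis loading), so the 95% does not give the power of this fit for it.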

Results

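The data comprised log2 expression values of 14884 genes in 8 clonal isolates of PC-3, an androgen-independent human prostate cancer line. A lentiviral vector carried RWDD4, a gene named for its RWD domain, into 4 of the clones, and the other 4 clones carried the empty vector. The design asks how expression differs between clones that overexpress RWDD4 and clones that do not. The median log2 value over all probe sets lay between 4.89 and 4.96 on all arrays. The groups did not overlap in it, with 4.8878 to 4.899 in the RWDD4 clones and 4.9198 to 4.9644 in the control clones. The SD over all probe sets also parted the groups, at 2.1941 to 2.2115 in the RWDD4 clones and 2.0967 to 2.1492 in the control clones. So did the median over the genes, at 6.0884 to 6.1257 in the RWDD4 clones and 5.8917 to 6.026 in the control clones. Across the 14884 genes, which are not independent replicates, values correlated at r = 0.991 to 0.993 between RWDD4 clones. The r was 0.980 to 0.992 between control clones and 0.913 to 0.974 between the groups.

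RWDD4 (Entrez gene 201965) was higher in every RWDD4 clone than in any control clone. Its level was 10.30 ± 0.29 (SD, n = 4) in the RWDD4 clones and 7.36 ± 0.58 (SD, n = 4) in the control clones. The difference was 2.94 (SE 0.25), or 7.67-fold, with an adjusted p of 5.98e-05 from limma and an exact permutation p of 0.0286, the smallest that 4 against 4 clones allow. Among all genes it had the largest rise and ranked 49 by p. Clones 17, 24 and 5 lay at 10.42, 10.45 and 10.46 and clone 6 at 9.87, and the control clones 2, 3, 4 and 5 at 6.64, 7.58, 7.21 and 8.0. The gene was read by 1 probe set; whether it reads the vector's transcript, the cell's own or both was not determined, and no other assay of the transcript or protein was used here.

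**Figure D1:**
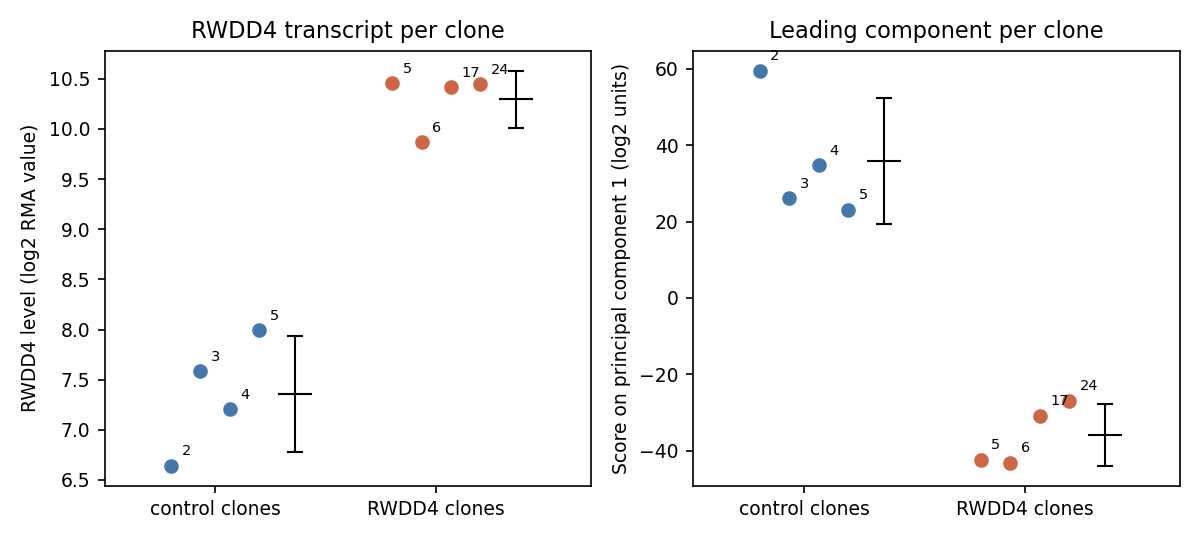
The left panel plots the log2 level of RWDD4 in each clone, and the right panel each clone's score on the leading principal component; points are clones with their numbers, and the bar beside each group is its mean ± SD (n = 4). The RWDD4 clones lie between 9.87 and 10.46 and the control clones between 6.64 and 8.0, and control clone 2 is the farthest from the other clones on the component.

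Beside RWDD4, the 12 named genes with the largest rises among those whose groups did not overlap rose 5.35-fold or more in the RWDD4 clones. TOP2A, a topoisomerase that untangles chromosomes, rose from 6.99 ± 0.54 to 9.90 ± 0.14 (SD, n = 4 each), which is 7.52-fold. NDC80 of the kinetochore rose 6.09-fold, SMC2 of condensin 6.05-fold, and the cytokinesis genes ECT2 and KIF23 6.12-fold and 5.35-fold. The spindle kinesins KIF14 and KIF11 rose 5.89-fold and 5.41-fold, and CKAP2, which binds spindle microtubules, 5.53-fold. The other genes of the leading 12 were GPX8, a peroxidase of the endoplasmic reticulum, which rose 7.07-fold, the membrane skeleton gene EPB41L3 at 6.30-fold, the zinc finger gene ZNF280C at 6.25-fold, and MTREX, a helicase of nuclear RNA decay, at 5.90-fold. Adjusted p values of these 12 genes ran from 5.26e-05 to 0.00241.

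The 12 genes named by the same rule for their falls were 2.62-fold or more lower in the RWDD4 clones. BST2, an interferon-induced membrane protein that tethers virus particles, fell by 3.21 (SE 0.52) on the log2 scale, which is 9.27-fold, from 7.23 ± 0.96 to 4.02 ± 0.97 (SD, n = 4 each). The protease inhibitors SLPI and CST4 were 5.75-fold and 3.97-fold lower, the chemokines CCL20 and CXCL8 4.56-fold and 2.75-fold lower, and the stress-induced cytokine GDF15 4.31-fold lower. ZC3H12A, a nuclease that degrades cytokine transcripts, was 3.57-fold lower. COXFA4L3 was 4.73-fold lower, CREB3L1, a transcription factor anchored in the endoplasmic reticulum, 3.32-fold, the calcium-binding protein gene S100A3 2.68-fold, the neurotensin receptor gene NTSR1 2.66-fold, and the interferon-induced IFI35 2.62-fold. BST2 lay at 3.41 to 3.66 in 3 of the RWDD4 clones, and the means of COXFA4L3 (3.67) and CCL20 (4.37) in the RWDD4 clones, and of KIF14 in the control clones (4.80), were also under the median of all probe sets. No background level was measured here, so whether the folds of these 4 genes are lower bounds was not determined. All 24 ranked genes passed with any 1 clone left out, under all 3 further scalings and with the trend over genomic span removed, and none passed with the within-group axis as a covariate.

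**Figure D2:**
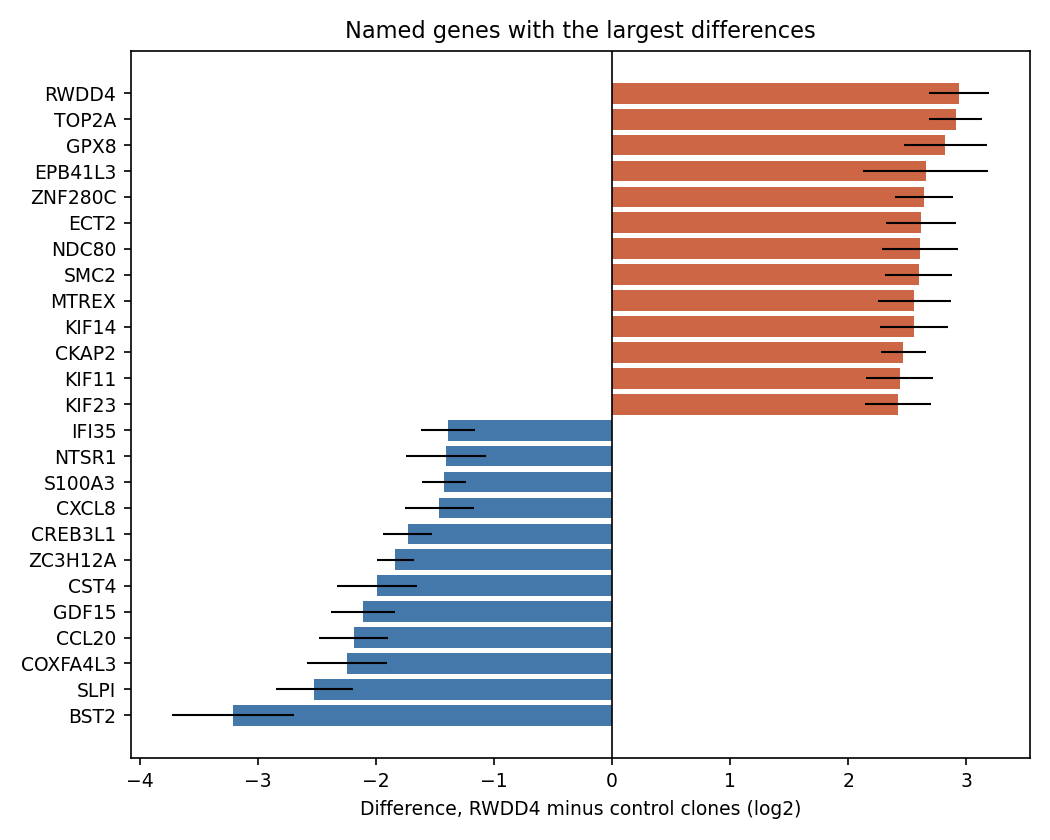
Bars give the log2 difference, RWDD4 minus control clones, of RWDD4 and of the 12 genes named in each direction, with SE as error bars (n = 4 per group). The rises run from 2.42 for KIF23 to 2.94 for RWDD4 and the falls from -1.39 for IFI35 to -3.21 for BST2.

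In all, 6955 of the 14884 genes changed (46.7%), 3741 up and 3214 down, by limma at an adjusted p under 0.05. Large changes were mostly rises: of the 1512 genes that changed at least 2-fold, 1450 rose and 62 fell. Groups did not overlap in 6666 genes (44.8%), against 2.86% by chance. Cyclic loess gave 3980 up and 2200 down, so the direction of the balance among all calls leaned further upward with that scaling, and quantile normalization gave 3429 up and 3694 down. With each array's position on the leading axis of within-group variation as a covariate, 1 gene passed, the non-coding LOC285889 at -2.25, chosen after its values were seen, and 1910 had an unadjusted p under 0.05.

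Rises were more frequent among genes of long genomic span, and falls among short genes. Across 11916 protein-coding genes, which are not independent replicates, the difference followed span with a Spearman rho of 0.40. In the decile of shortest genes 3.86% rose and 37.3% fell, in the ninth decile 51.1% rose and 8.73% fell, and in the decile of longest genes 43.4% rose and 5.54% fell. Of 8 small nuclear RNA genes, which act in splicing, 7 fell (median -0.73), a group picked after the data were seen, whose median was 0.39 with the within-group axis as a covariate. The same measure varied within the control group, where clone 2 minus clone 5 followed span with a rho of -0.30. After removal of each array's trend over span, 6946 genes passed, 5311 of them among the 6955.

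**Figure D3:**
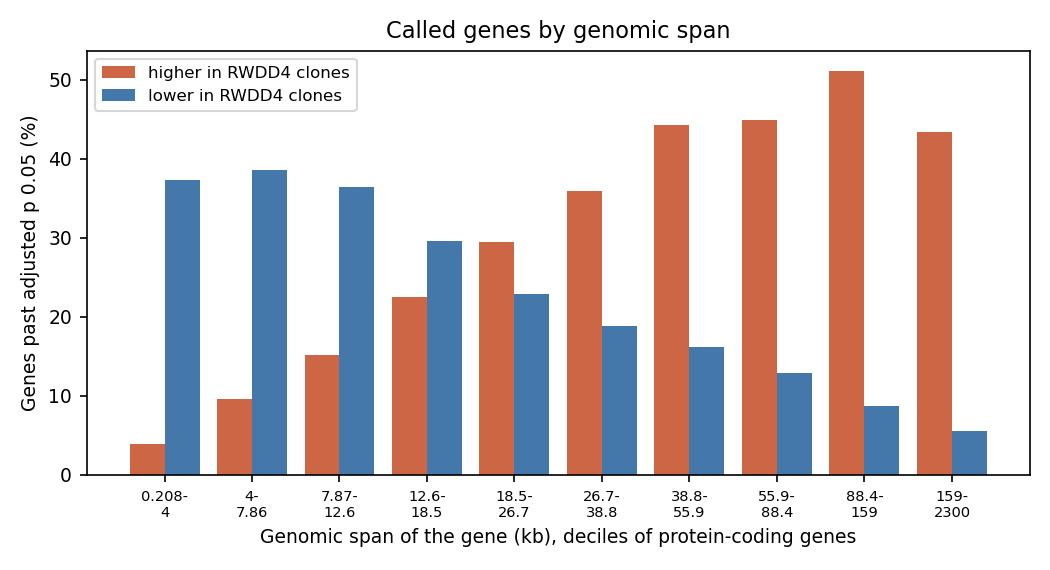
Bars give the percentage of protein-coding genes that passed an adjusted p of 0.05, higher or lower in the RWDD4 clones, in 10 deciles of genomic span in kb. The share that rose runs from 3.86% in the shortest genes to 51.1% in the ninth decile and 43.4% in the tenth, and the share that fell from 37.3% to 5.54% in the longest.

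The cell cycle lists held the most rises. In the mitosis list 14 of 17 measured members rose and none fell (median 1.79; 15 rose adjusted over the list alone), among them BUB1 and TTK of the spindle checkpoint at 2.27 and 2.32 and the cyclin CCNA2 at 2.06. AURKB, PLK1 and BIRC5 did not pass, at -0.02, 0.45 and 0.35. In the DNA repair list 9 of 10 rose (median 1.23; 9 adjusted over the list alone), with RAD51AP1 at 1.89, the helicase BRIP1 at 1.86, XRCC5 of end joining at 1.77 and the mismatch repair gene MSH6 at 1.30, and RAD54L lay at -0.004. The DNA replication list was split, with 8 of 17 up and 4 down: MCM6, MCM10 and the cyclin CCNE2 rose by 1.39, 1.11 and 1.22, while E2F1 and CDT1 fell by 0.74 and 0.63. With an estimated correlation the adjusted p was 0.594 for mitosis, 0.547 for DNA repair and 0.931 for DNA replication; with the preset correlation mitosis and DNA repair passed, at 3.56e-07 and 2.71e-05. The mean of the mitosis list was lowest in control clone 2, at 7.70, against 7.93 to 8.65 in the other control clones and 9.59 to 9.90 in the RWDD4 clones, and without that clone 14 of 17 members still rose (median 1.60).

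In the cytokine list 8 of 11 measured members fell and none rose (median -0.78; 11 fell adjusted over the list alone). Beside CCL20 and CXCL8, the adhesion receptor ICAM1 fell by 1.03, the chemokine CXCL2 by 0.86 and the interleukin IL11 by 0.74. The means of PTGS2 (3.45 to 3.12), which fell, and of CCL2 (3.49 to 2.98), which fell only adjusted over the list alone, were low. They lay under the median of all probe sets in both groups, and no background level was measured here. The means of the other members lay above it, except CCL20 in the RWDD4 clones. In the interferon response list 7 of 16 fell and none rose (median -0.42; 7 adjusted over the list alone), with ISG15 down by 1.95, the transcription factors IRF7 and IRF9 by 1.39 and 1.34 and OASL by 1.22; RIGI lay at 0.70 and IFIT1 at -1.16, neither past the test. RWDD4 clone 24 had a mean over this list of 6.71, within the range of the control clones (6.12 to 6.86), while the other RWDD4 clones lay between 5.47 and 5.81; without it 9 members fell (median -0.93), and without control clone 2 the median was -0.65. Camera gave the cytokine list a p of 0.0408 before adjustment and an adjusted p of 0.547 with an estimated correlation, and 0.000916 with the preset one; the interferon list had 0.931 and 0.137. The mean of the cytokine list was lower in every RWDD4 clone (exact permutation p 0.0286, the smallest possible, reached by 18 of the 34 lists, and 0.054 adjusted over them), and for the interferon list the exact permutation p was 0.143. Members that fell in the interferon list numbered 5 after median centring and 4 after cyclic loess.

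Of 15 epithelial genes 11 fell and none rose (median -0.40; 11 adjusted over the list alone), including the tight junction genes CLDN3, CLDN7 and CLDN4 at -0.86, -0.52 and -0.52 and the keratin KRT19 at -0.54; EPCAM lay at 0.13. Of 9 mesenchymal genes 4 rose and 1 fell, with fibronectin (FN1) at 1.31, vimentin (VIM) at 0.73, ZEB1 at 0.49 and ZEB2 at -0.24. The fall of ZEB2 did not pass after quantile normalization, median centring or cyclic loess, nor without control clone 2 or RWDD4 clone 24. Among 6 adhesion genes 3 rose, led by ALCAM at 1.31 and CD44 at 0.73, and MCAM fell by 0.41. MCAM did not pass without control clone 2, after median centring or after cyclic loess. With an estimated correlation the adjusted p was 0.594, 0.716 and 0.931 for these lists, and the epithelial list passed with the preset correlation (0.0200). With the within-group axis as a covariate the medians became -0.11 for the epithelial list, -0.23 for the mesenchymal list (from 0.42) and -0.11 for the adhesion list (from 0.38). The last 2 medians changed sign, but the list means there were -0.07 (SE 0.17) and -0.08 (SE 0.17), each smaller than its error. A reversal of these 2 lists was therefore not shown. With the span trend removed the medians of these 2 lists were 0.22 each.

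Of 10 measured genes related to RWDD4 by domain or to the kinase GCN2, 7 rose and 2 fell (median 1.03), with IMPACT, an inhibitor of GCN2, at 2.23, RWDD1 at 1.42, EIF2AK4, which encodes GCN2, at 1.32 and RWDD2B at 1.30; GCN1 lay at -0.02. The adjusted p was 0.594 with an estimated correlation and 0.0306 with the preset one. With the within-group axis as a covariate the median was 0.21 and IMPACT lay at 0.42. The amino acid stress list, targets of ATF4, moved both ways, with 5 of 13 up and 4 down: PSAT1 and ASNS of amino acid synthesis rose by 0.95 and 0.65, DDIT4 and SESN2 fell by 1.02 and 0.70, and ATF4 lay at -0.04. In the heat shock list 4 of 7 rose, with HSPH1 at 2.15, HSPA4L at 2.12 and the mitochondrial chaperone HSPD1 at 1.42, and HSPA1A lay at -0.07. In the unfolded protein list SEL1L rose by 1.40 and SDF2L1 fell by 0.78, of 7 measured. Of 12 ubiquitin and SUMO enzymes 6 rose, with the activating enzymes UBA6 and UBA3 at 1.76 and 1.1, and UBE2L6 fell by 1.0. Of 12 ribosomal protein genes 4 rose, led by RPS23 at 0.94 and RPS6 at 0.73, with a list median of 0.01; after quantile normalization 3 rose and 3 fell and the median was -0.17. The adjusted p of these 5 lists with an estimated correlation lay between 0.594 and 0.954.

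Growth factor receptors and regulators of apoptosis changed in both directions. In the growth factor list 6 of 16 rose and 3 fell: the ligand KITLG rose by 1.83, the receptors MET and EGFR by 1.78 and 1.43 and FGF2 by 1.31, while EPHA2 and FGFR2 fell by 0.49 and 0.44. Among apoptosis regulators 6 of 14 rose and 6 fell. The survival genes BCL2A1, BIRC2 and BCL2 rose by 1.7, 1.60 and 0.92, the pro-apoptotic PMAIP1 rose by 0.83, and the pro-apoptotic BID and BIK fell by 0.79 and 0.71. In the list of p53 targets, in a line that lacks p53, RRM2B rose by 2.08 and GDF15 fell by 2.11, with 3 of 9 up and 3 down, or 5 down after quantile normalization. In the immediate early list 6 of 16 fell and none rose (median -0.26), led by JUNB at -1.23 and IER3 at -0.64, and FOS fell by 0.35. With the span trend removed 3 fell and the median was -0.09. The median difference was also set against 10000 random lists of genes matched on mean level and genomic span. Of these, 42.17% had a lower median, and their middle value was -0.24, so the fall of this list did not stand out from such genes. Of 10 targets of TGF-beta and YAP 4 rose and 2 fell, with LTBP1 at 1.47 and AXL at 1.05 and AJUBA at -0.47; without control clone 2, and also after quantile normalization, 2 rose. With an estimated correlation the adjusted p was 0.547 for the immediate early list, against 0.0437 with the preset one, and between 0.716 and 0.945 for the other 4.

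In fatty acid synthesis 3 of 11 genes rose and 5 fell, with ACACA at 1.17, ELOVL5 at 0.87, ACSS2 at -0.64 and SREBF1 at -0.62. In cholesterol synthesis MVD and DHCR7 fell by 1.09 and 0.67 and SQLE rose by 0.52, with 1 of 11 up and 4 down. No member rose without control clone 2, without RWDD4 clone 24 or after quantile normalization, where 6 fell. In the respiratory chain list UQCRC2 rose by 1.42 and CYC1 fell by 0.39, with 3 of 7 up and 1 down, which became 1 up and 4 down after quantile normalization. In glycolysis LDHA rose by 0.57 and TPI1 fell by 0.50, of 8 measured. Of 12 hypoxia genes 4 rose and 2 fell, with KDM3A at 1.20 and NDRG1 at -0.53. In the oxidative stress list TXN and TXNRD1 of the thioredoxin system rose by 1.01 and 0.84 and OSGIN1 fell by 0.36, of 7 measured. All 4 drug metabolism genes measured changed, with RRM1 at 1.54, DCK at 0.47, CDA at -0.45 and GSTP1 at -0.44, and MT1F, at -0.74, was the 1 metallothionein of 7 that fell. The adjusted p with an estimated correlation lay between 0.594 and 0.931 in all 8 lists.

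Of 9 androgen and luminal genes FKBP5 rose by 0.87 and NDRG1 fell, and KLK3, the 1 measured member of the list of genes lost or silent in PC-3, lay at -0.05. Of 14 basal and squamous genes 4 fell and 1 rose, with DSC3 at 1.49 and KRT7 at -0.66. Of 12 neuroendocrine genes 4 fell by 0.24 to 0.38, led by SYP at -0.38, and 1 did so adjusted over the list alone, after median centring or after cyclic loess. Among stem cell genes CD24 rose by 0.64 and KLF4 and LGR6 fell by 0.38 and 0.33, of 10 measured, and in the protease list TIMP1 fell by 0.62 and ADAM17 rose by 0.92, also of 10. Of 6 blood cell markers 4 fell, by 0.30 to 0.42, led by CD14, against 2 after median centring or cyclic loess and 1 with the span trend removed. Of 8 stromal markers THY1 and VWF fell by 0.36 and 0.31, 0 of them adjusted over the list alone, after median centring or after cyclic loess. GAGE2A, CTAG2 and PRAME, the 3 cancer-testis genes measured, did not pass, at -0.15, -0.08 and 0.07, and no replication-dependent histone gene was among those measured. The 7 lists of this paragraph that were tested had an adjusted p between 0.547 and 0.931 with an estimated correlation.

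**Figure D4:**
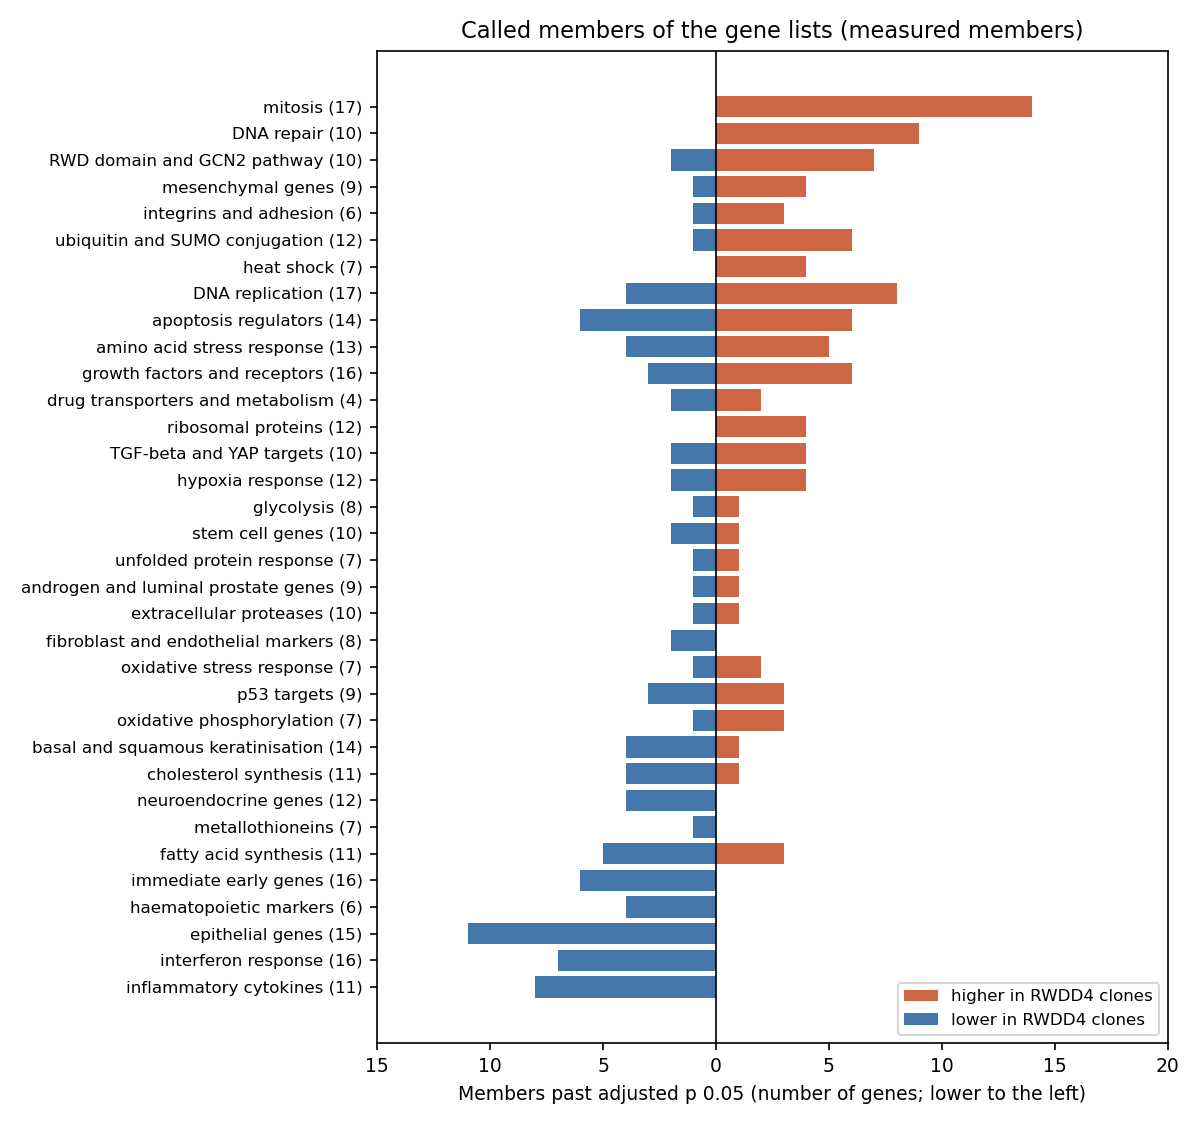
Bars give the number of members of each tested gene list that passed an adjusted p of 0.05, higher in the RWDD4 clones to the right and lower to the left, with the number measured in parentheses; lists are ordered by median difference. Mitosis, at the top, has 14 members higher of 17, and the cytokine list, at the bottom, 8 lower of 11.

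Over the 34 lists tested, camera with an estimated correlation called 0 at an adjusted p under 0.05, with 1 list at an unadjusted p under 0.05, while the preset correlation called 6 and fry 18. Adjusted over the list alone, the members up and down numbered 9 and 4 for DNA replication, 7 and 1 for ubiquitin and SUMO enzymes, 6 and 4 for amino acid stress, 4 and 1 for heat shock, 3 and 2 each for adhesion and the respiratory chain, 4 and 4 for TGF-beta and YAP targets, 3 and 4 for p53 targets and 2 and 2 for oxidative stress, and in lists with no such count given they were those over all genes. The mean and the median differed in sign in the hypoxia, fatty acid, respiratory chain, oxidative stress, unfolded protein, TGF-beta and YAP, androgen and stem cell lists. With the within-group axis as a covariate no member of any list passed. The median of the cytokine list was then -0.85, that of the mitosis list 0.73 and that of the DNA repair list 0.68. The medians of 8 of the 34 lists turned in sign: beside mesenchymal and adhesion genes these were amino acid stress (-0.29), the respiratory chain (0.14), androgen and luminal genes (0.10), p53 targets (0.01), apoptosis regulators (-0.06) and growth factors (-0.08). The means of these 8 lists had a p of 0.255 to 0.833 from that fit, so none could be told from 0.

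The median over genes of the SD within a group was 0.17 in the control clones and 0.14 in the RWDD4 clones, a ratio of 1.27 that was not tested, and without control clone 2 the control value was 0.14. The leading principal component held 79.2% of the variance and parted the groups, with control clone 2 at 59.5, the other control clones between 23.0 and 34.7, and the RWDD4 clones between -43.2 and -27.0.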

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

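The tests in this part were chosen only after the patterns they weigh had been seen, the removal of the span trend included, though the bound for the count of genes without that trend was set before that count was known. For the 3 gene lists weighed here, the test chosen first was the adjusted p of camera with an estimated correlation in each corrected fit. It gave 0.732 and 0.677 for mitosis and for the cytokine list, with the span trend removed and with the axis as a covariate, and 0.909 and 0.716 for the interferon list. It decided nothing, since camera called no list without a correction either, and tests on the mean of each list, with bounds set after the corrected medians had been seen, took its place.

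The breadth of the difference between the groups is the main pattern. Of the 35 splits of the 8 arrays into 4 and 4, only the real one called as many as 6955 genes, and the highest other count was 0. That is 1 of 35, the smallest share that 35 splits can give. It argues against chance at that share without excluding it. It does not bear on a difference in handling or growth that followed the groups. A trend over gene span is argued against as the whole source, since 6946 genes passed with the trend removed. An axis shared by arrays of both groups, such as RNA quality or growth state, stays open. Differences between clones of the same group correlated across genes with the group difference measured on the other arrays (median absolute r 0.357 over 12 pairs). The axis position correlated with group at -0.89, but the positions were computed from values that hold the group difference, so this is not separate support. For the same reason the covariate can take up part of a true group effect. RWDD4 lost its call with the axis as a covariate, with an adjusted p of 0.159 from limma. Its difference shrank and its error grew (2.94, SE 0.25, to 1.88, SE 0.43). An adjusted p also depends on the other genes, and only 1 gene passed in that fit. The lost call therefore does not rest on the values of RWDD4 alone. The vector's gene itself stays among the open explanations, untested.

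The rise of mitosis genes is not removed with the span trend, where the mean difference of the list was 1.57 against 1.56 without the correction. With the axis as a covariate it was 0.75 (SE 0.32, p 0.0373 from that fit, not adjusted over lists), 48.1% of the first value. This share was just under what the bound, set after the medians had been seen, asked to remain. The test therefore left open whether the rise comes from the axis or from the group, which overlap closely. An effect of RWDD4 on division and a faster growth of the RWDD4 clones at harvest could both give such a rise, and neither was tested.

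The cytokine list had a mean difference of -0.88, which was -0.71 with the span trend removed (exact permutation p 0.0286 both times, the smallest possible, reached before removal by 18 of the 34 lists and 0.054 when adjusted over them). The interferon list had -0.58 and -0.59 (exact permutation p 0.143 both times), and removing the trend did not make the interferon value smaller. Neither list mean passed the exact permutation test after adjustment. With 18 lists at the smallest possible p, 0.054 was the lowest adjusted value any list could reach. The cytokine list therefore could not have passed, whatever the size of its difference. With the axis as a covariate the cytokine list kept a mean difference of -0.89 (SE 0.27, p 0.00782 from that fit). The difference did not shrink there. The bound was set after the corrected medians had been seen, so meeting it could be foreseen and is no test of the axis. Whether the axis is the whole source of the cytokine difference stays open. The p was not adjusted over the 34 lists, and no member of the list passed in that fit. The interferon list had -0.73 (SE 0.60) there, an error nearly as large as the difference, so the axis and the group cannot be told apart for it. A lower inflammatory tone with RWDD4, or in the cell founding each clone, may underlie the cytokine values. These explanations arose from the same arrays, and neither was tested.

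A single clone lay far from the other 3 of its group in 21 of 368 groups of 4 examined, where chance gives about 18.4, or 1 in 20. In the RWDD4 clones, clone 24 stood apart for BST2 (5.46), ELOVL5 (8.44), BIRC2 (7.19), CDA (10.65) and DUSP5 (10.44). Clone 6 did so for RWDD4 (9.87), SDF2L1 (7.70), TPI1 (5.84) and CSF1R (5.41), and clone 5 for KDM3A (7.5). Clone 17 did so for KRT15 (5.48), NKG7 (5.71) and the means of the unfolded protein list (8.94) and the heat shock list (10.49). In the control clones, clone 2 stood apart for XRCC5 (8.82), BNIP3L (9.53), LTBP1 (8.42) and RPL10A (9.34), clone 5 for ISG15 (10.84), and clone 4 for IRF7 (10.07) and the mean of the ribosomal list (8.70).

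Probe sets that the annotation used does not list with a gene also differed: 6707 of 37519 passed (17.9%), 3243 higher and 3464 lower in the RWDD4 clones.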

How the results depend on the processing

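The span trend and axis alternatives were chosen after seeing the data. With all 53617 probe sets tested in place of genes, 14153 passed, and the count of genes changed at least 2-fold became 3059, since more features were tested. With the within-group axis as a covariate 1 gene passed, also 1 at least 2-fold, and the RWDD4 level differed by 1.88 (adjusted p 0.159, against 1.05e-05 to 0.00483 under its other alternatives); standard errors grow there because axis and group overlap, and the cause of the smaller differences was not tested. That fit reversed 16 named genes: ADAM17 -0.35, CD24 -0.37, CD44 -0.0019, CYC1 0.022, EGLN1 -0.37, ERO1A -0.30, FBN1 -0.23, FN1 -0.25, HSPA4L -0.082, KRT19 0.047, MVD 0.19, NRP1 -0.50, PSAT1 -0.027, SQLE -0.13, THBS1 -0.37 and TPI1 0.26, and 124 others of 143 kept their direction without passing. Camera called 0 lists under every other alternative run, against 6 with the preset correlation and 18 by fry. Leaving out 1 clone gave 5630 to 6768 genes, 1218 to 1693 at least 2-fold, 2.70 to 3.15 for RWDD4, and 1.03 to 1.39 for the ratio of spreads, lowest without control clone 2. The share of calls that rose was 53.8%, 64.4% with cyclic loess, 62.4% with median centring and 48.1% with quantile normalization. With these scalings, in that order, the median over genes of the shift in a gene's difference was 0.08, 0.05 and -0.04. Between 7 and 17 of 143 named genes lost their call in any 1 of the other alternatives that lost any, and none of these reversed. Signal over background was not used here, so no gene was set aside as undetected. No paired analysis was possible because the groups share fewer than 2 clone numbers, which only name clones.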

Other observations

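Gene families defined by the stem of the symbol, all chosen after seeing the data, added groups outside the lists. Of 22 nucleoporin genes (NUP) 17 rose and none fell (median 1.0), led by NUP155 at 1.95 and NUP107 at 1.85, and of 35 centrosomal genes (CEP) 25 rose and 2 fell (median 0.78), with CEP192 at 1.96 and CEP55 at 1.89. Of 16 genes of intraflagellar transport (IFT), which builds cilia, 10 rose and none fell (median 0.51), with IFT57 at 1.57. Of 467 zinc finger genes (ZNF) 199 rose and 67 fell (median 0.24). These medians were above 0 under all 3 further scalings, and with the within-group axis as a covariate no member passed and they shrank to 0.25 (NUP), 0.24 (CEP), 0.23 (IFT) and 0.10 (ZNF). Camera with an estimated correlation called 0 of 92 families. Of the 5 with an unadjusted p under 0.05 only ZNF was higher (0.0193). The other 4 were lower: keratin-associated proteins (KRTAP, 17 of 84 fell and 1 rose, p 0.0252), the stem S of S100 and S1PR genes (10 of 25 fell and 1 rose, p 0.0354), chemokines (CCL, 7 of 22 fell, p 0.0439) and claudins (CLDN, 10 of 24 fell and 1 rose, p 0.0475). With the span trend removed the KRTAP median went from -0.16 to 0.004, that of S from -0.20 to -0.09, that of CCL from -0.25 to -0.06 and that of CLDN from -0.18 to -0.14. After cyclic loess 11 KRTAP, 7 S, 2 CCL and 6 CLDN genes fell. Without control clone 2 these counts were 17, 8, 4 and 10. The p before adjustment was 0.138 for NUP, 0.0865 for CEP and 0.0607 for IFT, and the adjusted p of all 8 was 0.488.

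Of the genes on either side of RWDD4 in the reference order, 4 of the 10 nearest measured ones rose: TRAPPC11, next to it, by 1.80 (SE 0.18), CDKN2AIP by 0.89, PRIMPOL by 0.80 and WWC2 by 0.77. The median of the 10 was 0.26. Among all 11916 protein-coding genes 3578 rose, and whether the neighbours of RWDD4 differ from these was not tested. The interferon-induced membrane gene IFITM1, chosen after its values were seen, lay at 10.59 in RWDD4 clone 24, at 7.77 to 8.22 in the other RWDD4 clones and at 10.49 to 11.19 in the control clones, the order that ISG15 also showed, with 11.01 in clone 24, 8.94 to 9.35 in the other RWDD4 clones and 10.84 to 11.80 in the control clones.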
